A study of Mus musculus with 10 samples.

How the data were processed

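Gene-level read counts from regenerating mouse liver were analysed in 2 experiments, each from its own table. The tissue was liver left after partial hepatectomy (PHx), a surgical removal of most of the liver after which the remnant regrows. In the diet experiment, mice received a high-fat diet (HFD) or chow for 7 days before PHx, and liver was taken 40 hours after surgery from 3 mice per group. In the inhibitor experiment, mice received SSO at 40 mg/kg or its vehicle 1 day before PHx, and liver was taken 48 hours after surgery, with 4 libraries per group. The labels do not spell out SSO; in work on the fatty acid receptor CD36 the abbreviation commonly stands for sulfosuccinimidyl oleate, an inhibitor of fatty acid uptake through CD36.

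The values are whole-number counts of reads per Ensembl gene as deposited by the authors, with no normalization. The submitters' processing notes name Trim Galore 0.6.1, HISAT2 2.2.1, featureCounts 2.0.2 and DESeq2 and the build GRCm38 (mm10), without an order or settings. RNA was selected with polyT before library construction, per the labels' protocols. The strand setting, the treatment of reads that map to several places and the annotation release used for counting are not given in the sources used here. Each table held 55487 gene identifiers, of which 55141 matched a symbol in GENCODE M21, the annotation from which coordinates were also taken, and 213 shared a symbol with another identifier. Coordinates are 1-based on GRCm38.

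Each group has 1 record in the labels, and the columns of a table were assigned to groups by their names. The control columns carry only the letter C and a number, and were taken as chow or vehicle according to the experiment of the table. Columns were treated as replicate livers. For the diet experiment the design text names 3 individuals per group. For the inhibitor experiment nothing further says that the 4 columns of a group come from separate animals, so p-values there measure the spread between these libraries. No 2 libraries of a group agreed within sampling noise, so each was counted as a replicate.

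The total was 31.9 to 39.9 M counts per library in the diet experiment and 25.2 to 30.4 M in the inhibitor experiment. A count of 0 allows a level of up to 3 counts, which is 0.0770 to 0.0922 CPM in the diet experiment and 0.0817 to 0.136 CPM in the inhibitor experiment. Such floors and counting intervals cover counting error only, since PCR copies cannot be told from separate molecules. Because strand use is unknown, reads of genes whose exons overlap a gene on the other strand cannot be separated. Among 108 named genes, 6 shared more than 10% of their exon length in this way, which makes their levels uncertain: Ccnd1, Sds, Pltp, Fdft1, Dbp and Ccna2, with overlaps of 12.5% to 23.4%. The globin genes Hbb-bs and Hbb-bt are near-identical copies, and Cyp3a11 has close relatives, so their counts are uncertain too.

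Each comparison was fitted on its own table with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood test with robust spread, trimmed-mean (TMM) scaling and the filterByExpr filter on low counts. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. CPM values use TMM-scaled library sizes, and errors are the SD between libraries for CPM and the SE of the fit for log2 fold changes. Gene lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01 between genes, and adjusted over the lists with at least 5 measured members. Both the estimated-correlation form of camera and the self-contained test fry were run as alternatives. Fisher's exact test, two-sided, compared the calls of both experiments over genes tested in both, with 4 direction pairs adjusted together. No control library is shared between the experiments.

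The groups, the tests, 34 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The lists cover the cell cycle, lipid, bile acid and glucose metabolism, hepatocyte function, stress responses, inflammation and markers of the cell types of liver. The rule named, for each comparison, the targets Cd36, Ern1, Xbp1, Ccnd1, Mki67 and Ccnb1 whatever their values. It then took up to 5 genes with the highest and 5 with the lowest log2 fold change among called genes with a mean of at least 3 log2 CPM, no overlap between the groups and a symbol that is not a predicted gene. Last came up to 4 members of each called list by smallest p, members that went against their list, and the most abundant markers of other cell types. Genes named for another reason are said to have been chosen after their values were seen.

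The procedure was tested on simulated counts drawn from the means and library sizes of each table. Each gene was drawn on its own with the same dispersion in both groups. Correlated genes and a spread that differs between groups were therefore not simulated, and the rates may not hold for the real libraries. In the simulated diet comparison over 15235 genes, 47 of 100 genes changed by log2 1 and 91 of 100 changed by log2 2 were recovered. There 18 of 156 calls were false, a share of 11.5%, which is above the threshold of 0.05. In the simulated inhibitor comparison over 15342 genes, 25 of 100 and 76 of 100 were recovered, and 5 of 106 calls were false. The alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors or library size alone in place of TMM, no filter on low counts, a filter at 1 CPM, a test against a log2 fold change of 0.58, a fit without robust spread, the replicate number as a block and leaving out each library in turn. Sample quality weights in limma-voom and leaving out mitochondrially encoded genes were added after the data had been seen.

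The copy of the sorted-macrophage table held here was a fragment without a header. Its 12 value columns could not be matched to samples, and all 11915 complete lines held only 0, so the planned macrophage comparisons and the macrophage signatures in liver were not run. The single-cell libraries of sham and PHx liver were not analysed here.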

Results

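Liver transcripts were counted in 2 experiments on mice after partial hepatectomy (PHx). The diet experiment held 3 libraries from livers of mice fed a high-fat diet (HFD) for 7 days before surgery and 3 from mice kept on chow, all collected 40 hours after PHx. The inhibitor experiment held 4 libraries from mice given 40 mg/kg SSO 1 day before surgery, a name that commonly stands for an inhibitor of fatty acid uptake through CD36, and 4 from mice given vehicle, all collected 48 hours after PHx. Chow libraries held 39.0, 39.9 and 36.7 M counts and HFD libraries 33.9, 31.9 and 32.0 M. Vehicle libraries held 25.2, 26.3, 29.7 and 29.8 M counts and SSO libraries 28.3, 28.0, 29.6 and 30.4 M. Between 18104 and 21057 genes had counts in a library, with the lowest number in vehicle 2.

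The vehicle libraries were less alike than the others. Mitochondrially encoded transcripts took 4.99%, 22.5%, 11.5% and 9.15% of the counts in vehicle 1 to 4 and 15.2% to 17.6% in SSO libraries, against 6.56% to 9.96% in the diet experiment. On the first principal component, which held 45.8% of the variance, vehicle 1 and 3 lay at -97.3 and -92.8, vehicle 4 at -2.89 and vehicle 2 at 52.5, beyond the SSO libraries at 31.8 to 40.5. The median SD of a gene within its group, in log2 CPM, was 0.47 for vehicle and 0.25 for SSO. In the diet experiment it was 0.29 for chow and 0.20 for HFD. The labels describe all mice as male. Xist, a transcript of the inactive X chromosome, measured 698 to 1772 CPM in the 8 libraries of the inhibitor experiment, where the Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty had 0 counts. Xist measured 0 to 0.620 CPM and Ddx3y 55.0 to 76.3 CPM in the diet experiment. There Xist had 0 counts in each chow library and 9, 14 and 21 counts in HFD 1, 2 and 3. The source of these few reads was not tested, and handling that differed between the diet groups is not excluded. By these transcripts the livers of the inhibitor experiment were female, against the labels, and those of the diet experiment male.

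The diet comparison asked how acute lipid loading before surgery bears on the transcripts of the regenerating liver. By camera with its preset correlation, the mitosis list rose in HFD livers, while the cholesterol synthesis and the hepatocyte P450 and urea cycle lists fell (adjusted p = 0.331, 0.372 and 0.147 with an estimated correlation). Mki67, a nuclear protein of cycling cells (ENSMUSG00000031004, chromosome 7: 135689784 to 135716361, GRCm38), measured 10.8 ± 4.22 CPM in chow and 110 ± 15.2 in HFD livers (mean ± SD, n = 3 per group). Ccnb1, the cyclin that drives entry into mitosis (ENSMUSG00000041431, chromosome 13: 100778650 to 100786570), measured 4.31 ± 2.38 and 64.7 ± 10.9 CPM. The cholesterol synthesis gene Mvd (ENSMUSG00000006517, chromosome 8: 122433601 to 122443422) measured 29.4 ± 6.10 CPM in chow and 6.67 ± 1.74 in HFD livers. Cyp7a1, the rate-limiting enzyme of bile acid synthesis (ENSMUSG00000028240, chromosome 4: 6265612 to 6275633), measured 180 ± 34.6 and 48.6 ± 16.7 CPM. The log2 fold changes were 3.35 ± 0.28 (SE) for Mki67, 3.90 ± 0.40 for Ccnb1, -2.14 ± 0.23 for Mvd and -1.89 ± 0.26 for Cyp7a1. All 4 were called by edgeR (quasi-likelihood test with Benjamini-Hochberg adjustment), with adjusted p = 0.00103, 0.00642 and 0.00228 for the first 3 and an unadjusted p of 6.67e-05 for Cyp7a1.

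Of 15589 genes tested, edgeR called 361, of which 249 were higher and 112 lower in HFD livers, and 196 and 66 of these differed at least 2-fold. All 361 had groups that did not overlap; over all genes tested 21.9% did not overlap, where chance gives 10%. With scaling by library size alone, which moved the median of all genes by 0.15 on the log2 scale, 336 genes were higher and 60 lower. The number of calls was 681 without chow 1 and 184 without chow 2, and it was 86, 174 and 132 without HFD 1, 2 and 3. Among 33 gene lists tested with camera, 5 rose and 8 fell. With an estimated correlation camera called 0 lists, with 2 at an unadjusted p under 0.05, and fry called 3. These were the mitosis, the hepatocyte P450 and urea cycle and the dendritic cell lists (fry adjusted p = 0.0161, 0.0161 and 0.0290). The cholesterol synthesis and interferon lists were not called by fry (adjusted p = 0.0968 for both).

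Mitosis and G2/M genes rose in HFD livers as a group. Of 30 measured members edgeR called 26, and 29 when adjusted over the list alone, all higher, with a median log2 fold change of 3.14 (camera adjusted p = 1.32e-48; adjusted p = 0.331 with an estimated correlation). Cdc20, an activator of the anaphase-promoting complex, rose from 8.53 ± 7.40 to 138 ± 30.0 CPM, a 16.2-fold change, with an edgeR adjusted p of 0.0490. Ube2c, which works with that complex, rose by a log2 fold change of 3.92, the mitotic kinase Plk1 by 3.77 and the spindle protein Knstrn by 3.72 (edgeR adjusted p = 0.00923, 0.00460 and 0.0120). The cyclin Ccna2 rose from 4.74 ± 1.09 to 42.8 ± 5.89 CPM, and Aurka, a kinase of the spindle poles, from 7.41 to 43.8 CPM (edgeR adjusted p = 0.000444 and 0.000824). Birc5 and Cdca8, both parts of the chromosomal passenger complex, rose by log2 fold changes of 3.10 and 2.66 (edgeR adjusted p = 0.000503 and 0.000994). Mki67, Ccnb1, Plk1, Ccna2, Aurka, Birc5 and Cdca8 were called in each of 6 fits that left out 1 library. Without HFD 1 the number of called list members was 16. In edgeR fits without chow 3, or without HFD 1, 2 or 3, Cdc20 was not called (adjusted p up to 0.185), Knstrn was not called without chow 3 or HFD 1 (up to 0.0562) and Ube2c without chow 3 (0.0545).

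DNA replication and S phase genes moved less. The list rose with a median log2 fold change of 0.50 (camera adjusted p = 2.11e-06; adjusted p = 0.724 with an estimated correlation), and edgeR called 1 of 33 members, or 2 adjusted over the list alone. The called member was Tyms, thymidylate synthase, which rose from 9.58 ± 3.01 to 23.7 ± 6.01 CPM (edgeR adjusted p = 0.0488). Mcm10, a replication initiation factor, lay the other way at 56.2 ± 26.8 CPM in chow and 30.7 ± 1.10 in HFD livers (edgeR adjusted p = 0.230). The mean log2 CPM of the list was 3.76, 3.87 and 1.96 in chow 1, 2 and 3 and 3.82 to 4.18 in HFD libraries. Without chow 3 the list was not called (camera adjusted p = 0.0853). EdgeR called 2 members without chow 1 or chow 3 and 0 without any of the other 4 libraries. Tyms was not called without chow 2 or without HFD 1, 2 or 3 (edgeR adjusted p up to 0.163).

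Cholesterol synthesis genes fell in HFD livers. Of 25 measured members edgeR called 9, and 21 when adjusted over the list alone, all lower, with a median log2 fold change of -1.09 (camera adjusted p = 2.18e-17; adjusted p = 0.372 with an estimated correlation). Besides Mvd, Lss, which forms lanosterol, fell from 63.3 ± 7.58 to 25.5 ± 4.75 CPM (edgeR adjusted p = 0.00642). Fdps, farnesyl diphosphate synthase, fell from 12.9 to 1.96 CPM and Fdft1, squalene synthase, from 135 to 39.7 CPM (edgeR adjusted p = 0.0173 and 0.0186). Without 1 library the number of called members was 4 without chow 2, 18 without chow 3, 4 without HFD 1 and 2 without HFD 2 or HFD 3. Mvd and Lss were called in all 6 of these fits, while Fdps was not called without HFD 2 or 3, nor Fdft1 without HFD 1, 2 or 3 (edgeR adjusted p up to 0.0952 and 0.110).

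Hepatocyte P450 and urea cycle genes fell as a list, with 5 of 24 members called by edgeR, 16 adjusted over the list alone, and a median log2 fold change of -1.03 (camera adjusted p = 2.84e-12; adjusted p = 0.147 with an estimated correlation). Asl, argininosuccinate lyase of the urea cycle, fell from 807 ± 291 to 218 ± 23.2 CPM, and Arg1, the arginase that releases urea, from 1431 ± 222 to 621 ± 27.2 CPM (edgeR adjusted p = 0.00806 and 0.0106). Tat and Hpd, which break down tyrosine, fell from 1791 to 651 and from 1856 to 918 CPM (edgeR adjusted p = 0.0300 and 0.0439). Tdo2, which opens the tryptophan ring and was chosen after its values were seen, fell from 1174 to 572 CPM (edgeR adjusted p = 0.0471). The number of called members was 8 without chow 1 (7 lower, 1 higher), 3 without chow 2 and 0, 1 and 1 without HFD 1, 2 and 3. Asl was not called without HFD 1, Arg1 without any 1 HFD library, Tat without chow 2 or any 1 HFD library, and Hpd and Tdo2 without chow 2, chow 3 or any 1 HFD library (edgeR adjusted p up to 0.0698, 0.0893, 0.183, 0.242 and 0.233).

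Bile acid and glucose genes fell as lists with fewer called members. In the bile acid synthesis and transport list 3 of 18 members fell, 5 adjusted over the list alone, with a median log2 fold change of -0.33 (camera adjusted p = 0.00655; adjusted p = 0.476 with an estimated correlation). These were Cyp7a1, the organic anion carrier Slco1a4, which fell from 85.7 ± 31.1 to 14.2 ± 5.60 CPM, and the bile acid receptor gene Nr1h4, which fell from 125 ± 7.42 to 77.9 ± 9.05 CPM (edgeR adjusted p = 0.0238 and 0.0378 for the last pair). Slc10a1, the main bile acid uptake carrier, measured 479 ± 41.7 CPM in chow and 275 ± 54.1 in HFD livers (edgeR adjusted p = 0.0577; 0.0485 without chow 3). In the gluconeogenesis and glycogen list 2 of 16 members fell, 4 adjusted over the list alone, with a median of -0.57 (camera adjusted p = 0.00601; adjusted p = 0.372 with an estimated correlation). They were Slc37a4 and G6pc, the transporter and the catalytic subunit of the glucose-6-phosphatase system, which fell from 210 to 97.7 and from 259 to 138 CPM (edgeR adjusted p = 0.00469 and 0.0188). The bile acid list was not called without chow 1 (camera adjusted p = 0.145); its called members numbered 5 without chow 1 (3 lower, 2 higher), and 1, 5, 0 and 1, all lower, without chow 2, chow 3, HFD 1 and HFD 3. Those of the glucose list numbered 5 without chow 1 (4 lower, 1 higher), and 1, 5, 0, 1 and 1, all lower, without chow 2 and 3 and HFD 1, 2 and 3. Without HFD 1 none of Cyp7a1, Slco1a4, Nr1h4, Slc37a4 and G6pc was called, and edgeR adjusted p reached 0.0715, 0.106, 0.199, 0.0508 and 0.145 over all left-out libraries, among which chow 2 and HFD 3 also ended the calls of Slco1a4, Nr1h4 and G6pc and HFD 2 those of Nr1h4 and G6pc.

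Other called genes with large decreases were Cyp26a1, which degrades retinoic acid, from 41.8 ± 7.26 to 4.95 ± 3.00 CPM, Per3, a clock gene, from 23.9 ± 11.3 to 3.64 ± 0.944 CPM, and Gstt3, a glutathione transferase, from 44.8 ± 19.8 to 10.4 ± 3.22 CPM (edgeR adjusted p = 0.0396, 0.00983 and 0.0448). Per3 was not called without HFD 1 (edgeR adjusted p = 0.0698). Other clock genes differed between the groups as well, as given below, which bears on all differences between HFD and chow livers. Cyp26a1 was called only in the fit without HFD 3 and Gstt3 only in those without chow 1 or chow 3 (edgeR adjusted p up to 0.154 and 0.183 in the others).

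Interferon response genes rose as a list in HFD livers. The median log2 fold change of 22 members was 1.18, all above 0, and edgeR called 2, or 12 adjusted over the list alone (camera adjusted p = 2.09e-12; adjusted p = 0.372 with an estimated correlation). The called members were the antiviral genes Rsad2, from 2.72 ± 1.27 to 11.7 ± 3.21 CPM, and Cmpk2, from 2.24 ± 1.37 to 9.97 ± 0.892 CPM (edgeR adjusted p = 0.0215 and 0.0270). Irf7, a regulator of the response, measured 16.9 ± 2.99 and 28.1 ± 5.85 CPM (edgeR adjusted p = 0.0938). The number of called members was 12 without chow 1, 0 without chow 2, 1 without chow 3 and 0, 1 and 0 without HFD 1, 2 and 3. Rsad2 was not called without chow 2, chow 3, HFD 1 or HFD 3, nor Cmpk2 without chow 2 or any 1 HFD library (edgeR adjusted p up to 0.0978 and 0.128).

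Antigen presentation and dendritic cell lists rose without a called member. The MHC class II list had a median log2 fold change of 0.63 over 12 genes (camera adjusted p = 0.00612; adjusted p = 0.476 with an estimated correlation). Cd74, the invariant chain, measured 14.0 ± 3.05 CPM in chow and 22.6 ± 6.40 in HFD livers, and H2-Aa 5.10 ± 1.64 and 8.99 ± 2.18 CPM (edgeR adjusted p = 0.207 and 0.208). The dendritic cell list had a median of 0.47 over 11 genes (camera adjusted p = 0.0265; adjusted p = 0.372 with an estimated correlation). Siglech, a marker of plasmacytoid dendritic cells, measured 0.209 ± 0.158 and 0.916 ± 0.253 CPM and Bst2, an antiviral membrane protein, 82.5 ± 40.7 and 145 ± 18.8 CPM (edgeR adjusted p = 0.164 and 0.287). Bst2 is also a member of the interferon list. Another dendritic list member, Kmo, measured 308 to 351 CPM in chow and 436 to 445 CPM in HFD livers, far above Siglech. EdgeR called 0 genes in either list, also adjusted over the list alone, with 3 and 4 at an unadjusted p under 0.05; DESeq2 called 0 and 2, and limma-voom 0 and 0. The dendritic list was not called without chow 1 or chow 2 (camera adjusted p = 0.0515 and 0.0772), and Bst2 was called without chow 1 (edgeR adjusted p = 0.00487).

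Lists of lipogenesis, acute phase, sinusoidal endothelial and erythroid genes fell, again with 0 members called by edgeR. The medians were -0.77 over 20 lipogenic, -0.68 over 26 acute phase, -0.24 over 22 endothelial and -0.88 over 8 erythroid genes, with 0, 0, 1 and 1 members lower when adjusted over the list alone. Camera adjusted p-values were 0.00984, 0.0384, 0.00329 and 0.0265, and with an estimated correlation the adjusted p was 0.724, 0.768, 0.724 and 0.724. At an unadjusted p under 0.05, edgeR had 5, 2, 6 and 4 members lower and 1 lipogenic member higher; DESeq2 called 2, 1, 1 and 4 lower, and limma-voom 0 in each. Fasn, fatty acid synthase, measured 486 ± 417 CPM in chow and 149 ± 45.0 in HFD livers, and Thrsp, a lipogenic regulator, 176 ± 256 and 9.36 ± 5.11 CPM (edgeR adjusted p = 0.277 and 0.251). Hamp, the iron hormone hepcidin, measured 756 ± 439 and 271 ± 101 CPM (edgeR adjusted p = 0.166). The endothelial Wnt signals Wnt9b and Rspo3 measured 5.83 ± 3.01 and 7.07 ± 1.45 CPM in chow and 1.81 ± 0.392 and 4.47 ± 0.298 in HFD livers (edgeR adjusted p = 0.0622 and 0.197). The globins Hbb-bt and Hbb-bs measured 13.3 ± 7.69 and 147 ± 52.8 CPM in chow and 4.11 ± 1.25 and 75.0 ± 32.1 in HFD livers (edgeR adjusted p = 0.0909 and 0.251). Chow 1 stood highest in lipogenesis, with a mean log2 CPM of 7.64 against 6.42 and 6.09 in chow 2 and 3, and chow 3 in the acute phase, with 10.3 against 8.00 and 9.07 in chow 1 and 2. Camera did not call lipogenesis without chow 1 (adjusted p = 0.271), the acute phase without chow 2 or HFD 1 (0.0625 and 0.0693), the endothelial list without chow 3 (0.0853), or the erythroid list without chow 3, HFD 1 or HFD 3 (0.0501, 0.0786 and 0.0545). Without chow 3 the acute phase list lay the other way (camera adjusted p = 0.276), and without chow 1 edgeR called Wnt9b and Hbb-bt (adjusted p = 0.0454 and 0.0466). The fit without chow 1 called 3 acute phase, 2 endothelial and 1 erythroid members lower and 1 lipogenic member higher, and that without chow 3 called 1 lipogenic member lower.

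Of the 6 target genes fixed beforehand, Mki67 and Ccnb1 were called in the diet comparison and Cd36, Ern1, Xbp1 and Ccnd1 were not. Cd36, the fatty acid receptor (ENSMUSG00000002944, chromosome 5: 17781690 to 17888801), measured 56.5 ± 29.7 CPM in chow and 80.4 ± 41.1 in HFD livers (edgeR adjusted p = 0.762). Ern1, the stress sensor IRE1 (ENSMUSG00000020715, chromosome 11: 106394650 to 106487852), measured 79.6 ± 20.6 and 81.0 ± 14.7 CPM, and its target Xbp1 (ENSMUSG00000020484, chromosome 11: 5520659 to 5525893) 295 ± 64.0 and 352 ± 45.3 CPM, with log2 fold changes of 0.02 ± 0.21 and 0.25 ± 0.20 (SE), neither called by edgeR. The counts are totals per gene and do not separate spliced from unspliced Xbp1, so IRE1 activity was not measured. Ccnd1, the cyclin of entry into the cycle (ENSMUSG00000070348, chromosome 7: 144929931 to 144939925), measured 32.6 ± 14.9 and 55.8 ± 24.8 CPM (edgeR adjusted p = 0.498). Lists of Kupffer cell, monocyte, lipid-associated macrophage, lipid uptake and fatty acid oxidation genes were not called, with medians of 0.05, -0.32, 0.10, 0.18 and -0.12, of which the last turned positive with scaling by library size alone (camera adjusted p = 0.619, 0.813, 0.533, 0.581 and 0.598). For the monocyte list the camera test leaned upward against its median.

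**Figure D1:**
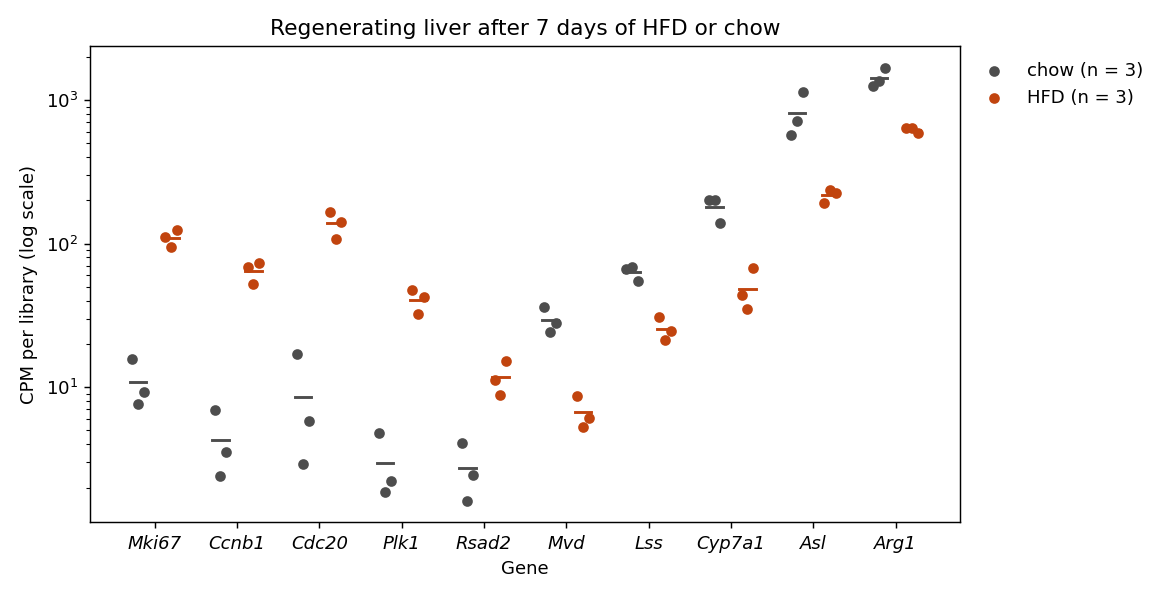
CPM per library on a log axis for 10 genes in chow (n = 3, grey) and HFD livers (n = 3, red) 40 hours after PHx; points are libraries and bars are group means. The groups do not overlap for any gene shown, and Mki67 lies near 10.8 CPM on average in chow and 110 CPM in HFD livers, with Mvd at 29.4 and 6.67 CPM.

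The inhibitor comparison asked what SSO before surgery changes in the liver 48 hours after PHx. Cd36 itself fell. By camera with its preset correlation, lists of lipogenesis and cholesterol synthesis rose and lists of S phase, mitosis and endoplasmic reticulum (ER) chaperones fell (adjusted p = 0.660, 0.426, 0.660, 0.670 and 0.660 with an estimated correlation). Of the members of the last 3 lists edgeR called 1 of 33, 2 of 30 and 1 of 27 lower, and 24, 24 and 20 when adjusted over the list alone. Cd36 measured 87.0 ± 14.0 CPM in vehicle and 35.8 ± 3.81 in SSO livers (mean ± SD, n = 4 per group), a log2 fold change of -1.28 ± 0.16 with an edgeR adjusted p of 0.0196. Fasn (ENSMUSG00000025153, chromosome 11: 120805846 to 120824547) rose from 466 ± 183 to 2710 ± 1195 CPM, and Acly, which supplies acetyl-CoA for fatty acid synthesis, from 188 ± 54.6 to 677 ± 61.3 CPM (edgeR adjusted p = 0.0313 and 0.0196). Pnpla3, a lipid droplet enzyme (ENSMUSG00000041653, chromosome 15: 84167837 to 84187236), rose from 2.54 ± 1.79 to 50.9 ± 15.6 CPM with a log2 fold change of 4.34 ± 0.49 (edgeR adjusted p = 0.0181). Chrna4, a nicotinic receptor subunit (ENSMUSG00000027577, chromosome 2: 181018380 to 181043546), rose from 18.5 ± 19.6 to 523 ± 93.0 CPM with a log2 fold change of 4.82 ± 0.71 (edgeR adjusted p = 0.0369). Every edgeR call named here was lost without vehicle 1 or without any 1 SSO library, and those of Fasn and Chrna4 also without vehicle 3, with adjusted p up to 0.103 for Cd36, Acly and Pnpla3 and up to 0.126 for Fasn and Chrna4. Fold changes kept their sign in all 8 fits, from -1.36 to -1.20 for Cd36.

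Of 15788 genes tested, edgeR called 71, of which 50 were higher and 21 lower in SSO livers, and 46 and 21 differed at least 2-fold; 3229 genes had an unadjusted p under 0.05. All 71 had groups that did not overlap; over all genes tested 11.8% did not overlap, where chance gives 2.86%. Single libraries decided this number: edgeR called 2646 genes without vehicle 2, 364 without vehicle 4, 16 without vehicle 3 and 0 without vehicle 1. It also called 0 without SSO 1, 2, 3 or 4, with 2472, 2276, 2658 and 2312 genes at an unadjusted p under 0.05, and 2068 without vehicle 1; DESeq2 was run on all 8 libraries only and called 1186. With scaling by library size alone, which moved the median of all genes by -0.16 on the log2 scale, 33 genes were higher and 4 lower. Counts of called genes are therefore given below with the list tests, of which 4 rose and 10 fell among 33. With an estimated correlation camera called 0 lists, with 2 at an unadjusted p under 0.05, and fry called 2. These were the lipogenesis and cholesterol synthesis lists (fry adjusted p = 0.0380 and 0.0110). The S phase, mitosis, ER chaperone and interferon lists were not called by fry (adjusted p = 0.0995, 0.185, 0.0931 and 0.389).

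De novo lipogenesis genes rose in SSO livers. Of 20 members edgeR called 7, and 15 when adjusted over the list alone, with a median log2 fold change of 1.71 (camera adjusted p = 3.89e-17; adjusted p = 0.660 with an estimated correlation). Besides Fasn, Acly and Pnpla3, Acss2, which makes acetyl-CoA from acetate, rose from 108 ± 58.0 to 607 ± 94.6 CPM, Gpam, which starts glycerolipid synthesis, from 158 ± 37.1 to 505 ± 56.4 CPM, and Aacs, which activates acetoacetate, from 52.3 ± 7.80 to 173 ± 42.3 CPM (edgeR adjusted p = 0.0269, 0.0196 and 0.0181). Elovl6, a fatty acid elongase chosen after its values were seen, rose from 58.0 to 241 CPM (edgeR adjusted p = 0.0369). The mean log2 CPM of the list was 6.45, 7.71, 6.17 and 6.96 in vehicle 1 to 4 and 8.52 to 9.02 in SSO libraries. The number of called members was 17 without vehicle 2, 5 without vehicle 3 and 0 without vehicle 1 or any 1 SSO library, where edgeR adjusted p reached 0.118 for Acss2, 0.103 for Gpam and Aacs and 0.138 for Elovl6, which was also lost without vehicle 3.

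Cholesterol synthesis genes rose with them. Of 25 members edgeR called 6, and 17 when adjusted over the list alone, with a median log2 fold change of 0.86 (camera adjusted p = 5.45e-14; adjusted p = 0.426 with an estimated correlation). Nsdhl, a sterol dehydrogenase, rose from 65.0 ± 2.01 to 171 ± 17.7 CPM, and Mvd from 49.9 ± 5.03 to 115 ± 18.7 CPM (edgeR adjusted p = 0.0181 and 0.0196). Acat2, which joins acetyl-CoA units, rose from 70.3 to 163 CPM and Pmvk, a kinase of the mevalonate route, from 25.6 to 65.5 CPM (edgeR adjusted p = 0.0369 and 0.0372). The number of called members was 16 without vehicle 2, 1 without vehicle 3 and 0 without vehicle 1 or any 1 SSO library. Over these fits edgeR adjusted p reached 0.103 for Nsdhl, 0.104 for Mvd and 0.170 for Acat2 and Pmvk, and the last 3 were also lost without vehicle 3.

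Bile acid and hepatocyte P450 lists rose without a called member. Their medians were 0.65 over 19 and 0.38 over 24 genes (camera adjusted p = 2.73e-06 and 0.00112; adjusted p = 0.670 and 0.793 with an estimated correlation). EdgeR called 0 in each, or 1 and 0 adjusted over the list alone, with 7 and 2 higher at an unadjusted p under 0.05; DESeq2 called 3 and 1, and limma-voom 0 and 0. The bile salt export pump Abcb11 measured 290 ± 83.5 CPM in vehicle and 635 ± 50.7 in SSO livers, and Cyp27a1, of the alternative bile acid pathway, 235 ± 115 and 504 ± 63.2 CPM (edgeR adjusted p = 0.0843 and 0.120). The drug-metabolising Cyp3a11 measured 1572 ± 951 and 3849 ± 572 CPM and Cyp1a2 1930 ± 1076 and 3697 ± 685 CPM (edgeR adjusted p = 0.150 and 0.208). Without vehicle 2 edgeR called all 4 of these genes (adjusted p = 0.0128, 0.00583, 0.0286 and 0.0179), and Abcb11 also without vehicle 4 (0.0309); called members numbered 5 and 4 without vehicle 2 and 2 and 0 without vehicle 4.

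Cell cycle genes fell in SSO livers as lists. The S phase list had a median log2 fold change of -1.43 and the mitosis and G2/M list of -1.45 (camera adjusted p = 1.89e-12 and 1.84e-11; adjusted p = 0.660 and 0.670 with an estimated correlation). EdgeR called 1 of 33 and 2 of 30 members, and 24 and 24 when adjusted over the list alone, all lower. E2f1, a transcription factor of S phase entry, fell from 12.7 ± 4.37 to 3.36 ± 0.781 CPM, the mitotic kinase Cdk1 from 16.1 ± 6.50 to 3.44 ± 1.49 CPM and the spindle protein Aspm from 2.90 ± 1.13 to 0.444 ± 0.139 CPM (edgeR adjusted p = 0.0369, 0.0396 and 0.0396). Outside these lists Stmn1, a microtubule regulator, fell from 21.2 ± 6.36 to 6.34 ± 2.33 CPM and the DNA repair enzyme Ung from 18.9 ± 2.25 to 6.40 ± 1.83 CPM (edgeR adjusted p = 0.0416 and 0.0269). Rrm1, a subunit of ribonucleotide reductase, measured 28.4 ± 10.0 and 11.2 ± 1.07 CPM and Cdc20 8.86 ± 5.40 and 1.77 ± 0.726 CPM (edgeR adjusted p = 0.0650 and 0.0793). Mki67 measured 30.7 ± 12.1 CPM in vehicle and 16.5 ± 0.860 in SSO livers, Ccnb1 6.71 ± 3.77 and 1.62 ± 0.771 CPM, and Ccnd1 73.5 ± 81.6 and 6.23 ± 1.43 CPM (edgeR adjusted p = 0.130, 0.106 and 0.106). The mean log2 CPM of the mitosis list was 2.74, 1.29, 2.95 and 2.97 in vehicle 1 to 4 and 1.10 to 1.48 in SSO libraries. Without vehicle 2, edgeR called 24 S phase and 27 mitosis members, among them Rrm1, Cdc20, Mki67, Ccnb1 and Ccnd1 (adjusted p = 0.000498, 0.00344, 0.00265, 0.00727 and 0.0208). Without vehicle 4 it called 8 and 2, with Ccnd1 at an adjusted p of 0.0370, and without vehicle 1, vehicle 3 or any 1 SSO library 0 and 0, where the calls of E2f1, Cdk1, Aspm, Stmn1 and Ung were lost (adjusted p up to 0.138, 0.174, 0.170, 0.191 and 0.133).

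Immediate early genes fell as a list with 0 of 14 members called by edgeR, 8 adjusted over the list alone and a median log2 fold change of -1.63 (camera adjusted p = 0.00112; adjusted p = 0.670 with an estimated correlation). At an unadjusted p under 0.05, 10 were lower; DESeq2 called 8 and limma-voom 0. Junb measured 44.6 ± 18.8 CPM in vehicle and 15.8 ± 2.55 in SSO livers and Egr1 58.4 ± 48.1 and 7.85 ± 2.00 CPM (edgeR adjusted p = 0.0674 and 0.106). Both were called without vehicle 2 (edgeR adjusted p = 0.0156 and 0.0351) or vehicle 4 (0.00412 and 0.00944), where 9 and 5 members were lower, with 1 higher without vehicle 2.

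ER stress genes fell as lists. In the IRE1-XBP1 and ER chaperone list edgeR called 1 of 27 members, and adjusted over the list alone 20 were lower and 1 higher, with a median log2 fold change of -0.83 (camera adjusted p = 6.50e-11; adjusted p = 0.660 with an estimated correlation). The called member was the ER chaperone gene Creld2, which fell from 140 ± 59.7 to 31.6 ± 7.40 CPM (edgeR adjusted p = 0.0390). Sdf2l1 and Dnajb11, which serve protein folding in the ER, measured 110 ± 28.5 and 134 ± 31.6 CPM in vehicle and 44.7 ± 14.4 and 65.9 in SSO livers (edgeR adjusted p = 0.0779 and 0.0831). Ern1 measured 62.2 ± 7.03 and 67.5 ± 1.79 CPM, and Xbp1 234 ± 51.5 and 176 ± 11.6 CPM (edgeR adjusted p = 0.648 and 0.264). Here too these are totals per gene, which do not measure Xbp1 splicing. The ATF4-CHOP list had a median of -0.92 with 0 of 19 members called by edgeR, and 10 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0275; adjusted p = 0.670 with an estimated correlation). At an unadjusted p under 0.05, 11 were lower and 2 higher; DESeq2 called 8 lower and 1 higher, and limma-voom 0. Ddit3, which encodes CHOP, measured 28.5 ± 10.7 and 11.1 ± 1.61 CPM and the stress hormone Gdf15 23.3 ± 8.95 and 7.87 ± 2.62 CPM (edgeR adjusted p = 0.0648 and 0.0674). Hsph1, a cytosolic heat shock protein, fell from 74.4 ± 27.9 to 26.9 ± 3.37 CPM (edgeR adjusted p = 0.0375). Camera did not call the ATF4-CHOP list without vehicle 4 (adjusted p = 0.139). Sdf2l1, Dnajb11, Ddit3 and Gdf15 were called by edgeR without vehicle 2 (adjusted p = 0.00625, 0.00586, 0.00176 and 0.00901), when 18 and 10 members of the lists were lower, and all but Dnajb11 without vehicle 4 (0.0492, 0.0483 and 0.0212), when 2 and 3 were. The calls of Creld2 and Hsph1 were lost without vehicle 1, vehicle 3 or any 1 SSO library (edgeR adjusted p up to 0.180 for both).

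Lists of lipid-associated macrophage, monocyte and matrix genes fell, and their levels split the vehicle libraries. The Kupffer cell list, of resident macrophages, was not called, with a median log2 fold change of -0.02 and 10 of 20 genes above 0 (camera adjusted p = 0.149, leaning upward). The monocyte list had a median log2 fold change of -2.15 over 17 genes, the stellate cell and matrix list -0.75 over 21 and the lipid-associated macrophage list -0.93 over 24 (camera adjusted p = 0.00792, 0.00124 and 2.83e-05; adjusted p = 0.793, 0.793 and 0.670 with an estimated correlation). The mean log2 CPM of the monocyte list was 5.60, 2.70, 5.76 and 3.00 in vehicle 1 to 4 and 2.69 to 2.96 in SSO libraries, and that of the matrix list 4.98, 3.12, 4.95 and 3.65 against 3.14 to 3.40. EdgeR called 0, 0 and 1 members, and 11, 7 and 16 were lower adjusted over the list alone, with 1 member of the lipid-associated macrophage list higher. At an unadjusted p under 0.05, edgeR had 12, 10 and 17 lower; DESeq2 called 8, 8 and 10 lower, and limma-voom 0, 0 and 1. The called member of the lipid-associated macrophage list was Cd36. It measured 101, 72.4, 77.9 and 96.3 CPM in vehicle 1 to 4, so it did not split these libraries as the monocyte list did. Its fall in whole liver does not by itself show a change in macrophages. Ccr2, the receptor that brings monocytes into tissue, measured 13.5 ± 9.72 CPM in vehicle and 3.24 ± 0.864 in SSO livers, and the lysozyme gene Lyz2 111 ± 90.7 and 4.95 ± 5.61 CPM (edgeR adjusted p = 0.112 and 0.129). Lyz2 was uneven between SSO libraries, at 0.0371, 11.3, 0.428 and 8.01 CPM in SSO 1 to 4. Ccr2 measured 3.12, 2.08, 3.99 and 3.79 CPM there, so the Lyz2 level did not follow Ccr2. The lipid droplet coat gene Plin2 measured 428 ± 128 and 202 ± 19.5 CPM and Anxa5 149 ± 40.6 and 78.2 ± 8.66 CPM (edgeR adjusted p = 0.0866 and 0.105). The collagen genes Col1a1 and Col3a1 measured 102 ± 83.0 and 116 ± 76.5 CPM in vehicle and 13.3 ± 3.70 and 32.6 ± 6.64 in SSO livers (edgeR adjusted p = 0.111 for both). Without vehicle 2, edgeR called 7, 11 and 17 members lower, with Ccr2, Plin2, Anxa5, Col1a1 and Col3a1 among them (adjusted p = 0.00400, 0.00827, 0.00388, 0.00392 and 0.00727), and without vehicle 4 it called 3, 1 and 5, with Plin2 at 0.0365. Without vehicle 1 or any 1 SSO library it called 0 in all 3 lists, and without vehicle 3 only Cd36.

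Interferon response and cytokine lists fell as well. The interferon list had a median log2 fold change of -2.43 with 0 of 22 members called by edgeR and 19 lower adjusted over the list alone (camera adjusted p = 1.22e-07; adjusted p = 0.670 with an estimated correlation). At an unadjusted p under 0.05, 20 were lower; DESeq2 called 17 and limma-voom 0. Its mean log2 CPM was 7.02, 6.21, 7.14 and 3.49 in vehicle 1 to 4 and 3.52 to 4.50 in SSO libraries. Rsad2 measured 136 ± 117 CPM in vehicle and 7.58 ± 3.01 in SSO livers, and Ifit1, another antiviral gene, 199 ± 129 and 15.6 ± 5.66 CPM (edgeR adjusted p = 0.0866 and 0.106). The cytokine and chemokine list had a median of -1.49 with 1 of 16 members called by edgeR and 4 adjusted over the list alone (camera adjusted p = 0.0253; adjusted p = 0.793 with an estimated correlation). The called member was Il6, a cytokine that primes hepatocytes for division, with 101 counts over the vehicle and 5 over the SSO libraries, a ratio of 18.9 with a 95% counting interval of 7.82 to 59.3 (edgeR adjusted p = 0.0369). The neutrophil chemokine Cxcl1 measured 28.1 ± 18.2 and 6.44 ± 3.13 CPM and the interferon-induced Cxcl10 62.5 ± 57.7 and 4.78 ± 2.02 CPM (edgeR adjusted p = 0.106 and 0.113). Without vehicle 4 edgeR called 19 interferon members, including Rsad2 and Ifit1 (adjusted p = 0.00439 and 0.000783), along with Cxcl1 and Cxcl10 (0.0252 and 0.00842). Without vehicle 2 it called 3, with Rsad2 at 0.0290, and Cxcl1 (0.0315). Called cytokine members numbered 5 and 4 without vehicle 2 and 4. Camera did not call the cytokine list without vehicle 3 (adjusted p = 0.152), and edgeR did not call Il6 without vehicle 1, vehicle 3 or any 1 SSO library (adjusted p up to 0.170).

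Among the remaining genes that passed the rule, Lmntd2, which encodes a lamin tail domain protein, rose from 3.58 ± 1.40 to 19.7 ± 3.47 CPM, and Slc25a30, a mitochondrial carrier, fell from 27.8 to 6.51 CPM (edgeR adjusted p = 0.0181 and 0.0408). Both calls were lost without vehicle 1 or any 1 SSO library, and that of Slc25a30 without vehicle 3 (edgeR adjusted p up to 0.103 and 0.172).

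**Figure D2:**
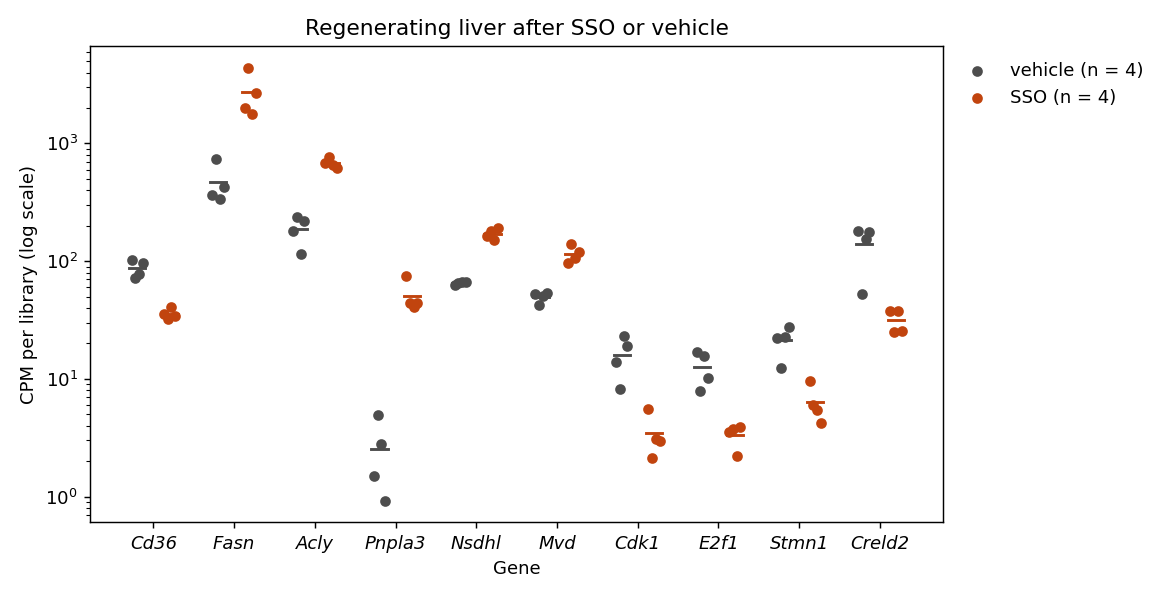
CPM per library on a log axis for 10 genes in vehicle (n = 4, grey) and SSO livers (n = 4, red) 48 hours after PHx; points are libraries and bars are group means. The groups do not overlap for any gene shown, with Cd36 at means of 87.0 and 35.8 CPM and Fasn at 466 and 2710 CPM.

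**Figure D3:**
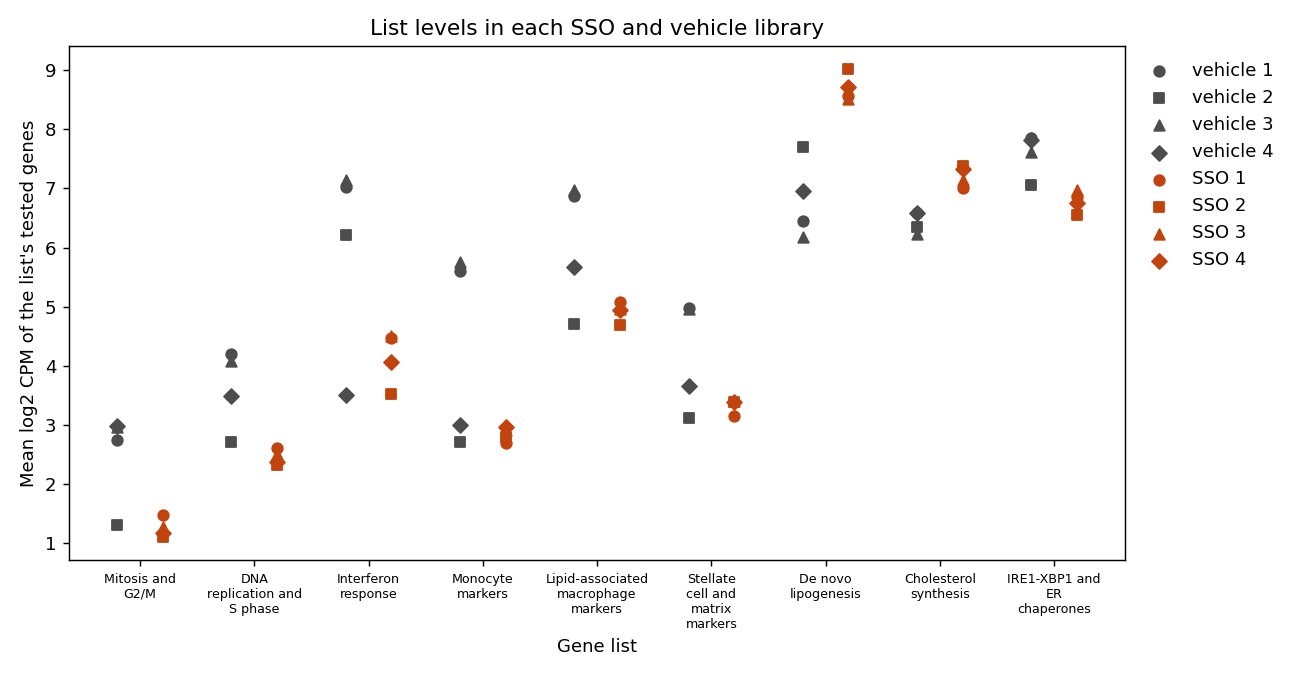
Mean log2 CPM of the measured genes of 9 lists in each vehicle (grey) and SSO library (red), with a marker shape for each library number. Monocyte genes lie at 5.60 and 5.76 in vehicle 1 and 3 and at 2.70 and 3.00 in vehicle 2 and 4, while lipogenesis genes lie at 8.52 to 9.02 in all 4 SSO libraries, above each vehicle library.

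The fold changes of the diet and inhibitor experiments were set beside each other. The experiments share no library and differ in time after surgery and in sex, with male livers in the diet and female livers in the inhibitor experiment by the sex-linked transcripts given above. Among 14905 genes tested in both, 11 were called in both, all in opposite directions. Of these 8 were higher with HFD and lower with SSO: Aspm, Cdk1, Ckap2, Ect2, Iqgap3, Spag5, Stmn1 and the predicted gene Gm42047, where independent calls would give 0.308 (Fisher's exact p = 2.79e-10, adjusted 1.11e-09). The other 3, Lss, Mvd and Pmvk, were lower with HFD and higher with SSO, where 0.362 would be given (Fisher's exact p = 0.00563, adjusted 0.0113). Of these genes Ckap2, Ect2, Iqgap3, Spag5 and Gm42047, as well as Lss in the SSO comparison and Aspm, Cdk1, Stmn1 and Pmvk in the diet comparison, were chosen after their values were seen. Fisher's test takes genes as independent, but the estimated correlation between genes of the mitosis list was 0.67 with HFD and 0.64 with SSO. Its p-values are thus too small for linked genes and do not measure the spread between libraries. Iqgap3, a scaffold protein, had log2 fold changes of 3.57 with HFD and -1.97 with SSO, and Ect2, an exchange factor needed for cytokinesis, of 3.23 and -2.53 (edgeR adjusted p = 0.00797 and 0.0196 for Iqgap3 and 0.000444 and 0.0462 for Ect2). No gene was called in the same direction by edgeR in both, where independent calls would give 0.796 higher and 0.140 lower genes; with DESeq2, 186 genes were called in both and 182 of them were opposite. Of 242 genes higher with HFD, 214 had a negative fold change with SSO, against 53.7% of all genes, and of 110 lower with HFD, 90 had a positive one. Across the 14905 genes, which are not independent replicates, Pearson's r was -0.31 and Spearman's rho -0.27. None of the 11 genes was called with SSO by edgeR without vehicle 1, vehicle 3 or any 1 SSO library (adjusted p up to 0.207). With HFD, edgeR did not call Cdk1 and Stmn1 without chow 2 or HFD 1 (adjusted p up to 0.0833 and 0.0602), nor Spag5 and Pmvk without chow 2 or any 1 HFD library (0.116 and 0.106). At an adjusted p under 0.1 from edgeR the overlap was 39 genes, all opposite.

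**Figure D4:**
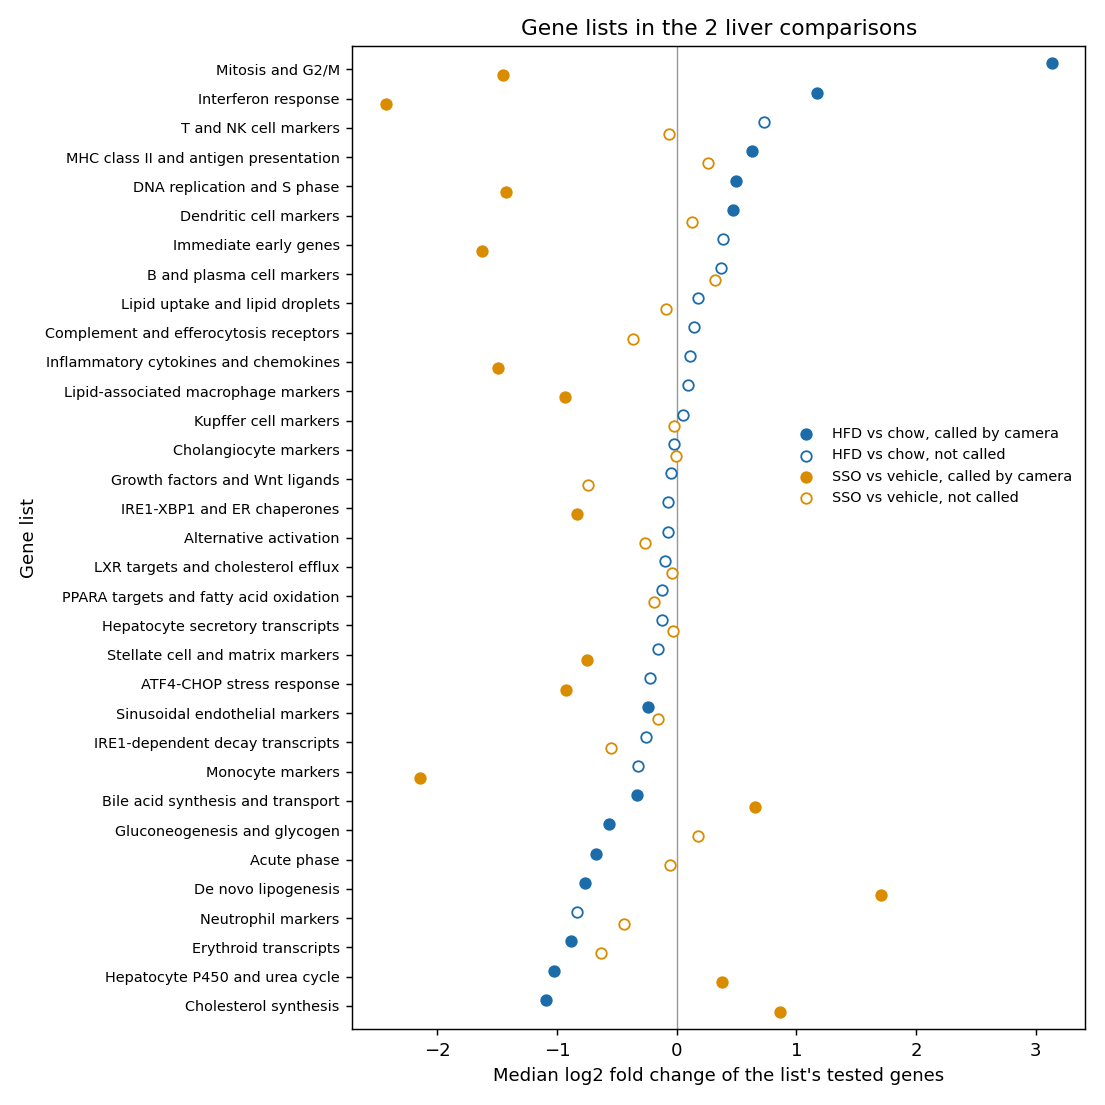
Median log2 fold change (x axis) of each gene list (y axis) in HFD against chow (blue) and SSO against vehicle (orange); filled points were called by camera. Mitosis genes lie at 3.14 and -1.45, cholesterol synthesis genes at -1.09 and 0.86, and lipogenesis genes at -0.77 and 1.71; medians near 0 of 8 HFD lists and 1 SSO list, none called, change sign with scaling by library size alone.

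**Figure D5:**
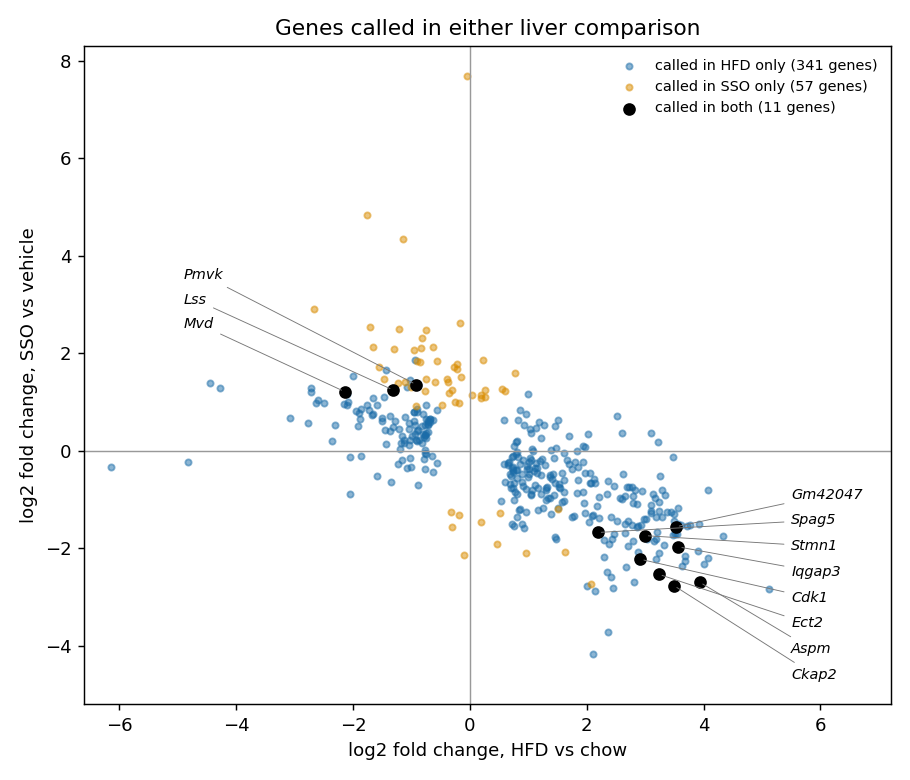
Log2 fold change with HFD (x axis) and with SSO (y axis) of each gene called in either comparison and tested in both, 341 called with HFD only (blue), 57 with SSO only (orange) and 11 in both (black, named). All 11 lie in the upper left or lower right quadrant, such as Mvd at -2.14 and 1.21 and Aspm at 3.93 and -2.70.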

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

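Of the tests in this part, those of non-parenchymal cells, of a more fed state and of vehicle 2 as an SSO library were chosen only after the results they concern had been seen, and the clock index was chosen after the fall of the clock gene Per3 with HFD had been seen and leaves Per3 out.

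Mitotic genes rose in HFD livers, and time of day at sampling may take part in this. A clock index, the mean log2 CPM of 4 clock genes that peak with Arntl minus that of 8 that peak with Dbp, was 2.63 higher in HFD than in chow livers (95% interval 1.54 to 3.71, n = 3 per group, groups not overlapping, exact permutation p = 0.1, the smallest possible here). Of its genes edgeR called Dbp, Tef and Ciart, with log2 fold changes of -2.64, -1.65 and -4.27 (adjusted p = 0.00576, 0.0287 and 0.0207). None of the others was called, and among these only Dbp was called in each of 6 fits with 1 library left out. A different hour of sampling would give this, and so would an effect of the diet on the clock, which the design does not separate. The clock difference lies between the same groups as every other HFD change reported here, so it limits those too. A rise of all non-parenchymal cells alike in HFD livers is argued against by the list medians. The lowest median log2 fold change of the Kupffer, endothelial and stellate lists was -0.24 (endothelial), while that of the mitotic list was 3.14. The 95% interval of -0.43 to -0.11 for the endothelial median comes from resampling its genes and does not measure the spread between mice. More cells of single types stay open. The medians of the MHC class II, dendritic cell and T and NK cell lists were 0.63, 0.47 and 0.73 (camera adjusted p = 0.00612, 0.0265 and 0.211), with 0 members called by edgeR. The last list had 6 of 17 genes measured, and the dendritic list shares Bst2 with the interferon list. These medians therefore do not show more of such cells. The hour of sampling and the diet, the only biological explanation given by the design, also stay open.

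Lipogenic genes rose in SSO livers, and neither technical explanation tested could be settled. The clock index differed by -0.60 between SSO and vehicle livers (95% interval -1.93 to 0.73, n = 4 per group, exact permutation p = 0.343). The median log2 fold change of 12 fasting-induced genes was -0.0292, with 6 genes below 0, so a more fed state in SSO mice is neither shown nor excluded. Its 95% interval of -0.56 to 0.35 comes from resampling the genes and does not measure the spread between libraries. SSO itself is the biological explanation given by the design.

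The number of genes called with SSO depended on single vehicle libraries, above all vehicle 2. Whether vehicle 2 could be an SSO library was not settled. On 2 lists it lay outside the SSO range on the vehicle side. Its mean log2 CPM was 6.35 for cholesterol synthesis (other vehicle libraries 6.23 to 6.58, SSO 7.01 to 7.39, a further SSO library expected from 6.61). For lipogenesis it was 7.71 (6.17 to 6.96, 8.52 to 9.02 and from 7.91). Both lists had been found to separate the groups with vehicle 2 counted as vehicle, so they cannot decide this alone. The test on these 2 lists was the last of 3, after 2 counts over 100 genes had not decided. Vehicle 2 was nearer the other vehicle libraries in 25. Vehicle 1, 3 and 4 were so in 99, 85 and 21, each over the 100 genes of its own fit. This count thus does not single out vehicle 2, as vehicle 4 also lay nearer the SSO libraries in most genes. Vehicle 2 lay outside the SSO range on the vehicle side in 47, against 23 to 48 for the SSO libraries. It also lay on that side for S phase (2.71, SSO 2.32 to 2.61), interferon (6.21, 3.52 to 4.50) and ER chaperone genes (7.05, 6.55 to 6.98). It lay inside the SSO range for mitosis (1.29, 1.10 to 1.48), monocyte (2.70, 2.69 to 2.96) and lipid-associated macrophage genes (4.70, 4.69 to 5.08). For matrix genes it lay below that range, away from the other vehicle libraries (3.12, 3.14 to 3.40). Mitochondrially encoded reads stay open: edgeR called the same 71 genes with these genes left out, but this moved so little that it tests nothing about the 22.5% such reads take in vehicle 2. A vehicle 2 that differs in some other way also stays open, and no biological explanation was tested.

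Other splits of the libraries were tested as a check on chance. For the diet experiment 10 splits are too few for a share under 0.05: the real split gave 361 genes and the highest other 0, so 1 of 10 gave as many, and for gene lists the real split gave 13 and the highest other 19, with 4 of 10 giving as many. For genes in the inhibitor experiment the real split gave 71 and the highest other 0, so 1 of 35 gave as many, the smallest share possible. The other splits mix both groups, which adds the difference between the groups to the spread within them. Few calls there are therefore likely in any case, and chance is not excluded. For its gene lists chance cannot be excluded, since the real split gave 14, the highest other 26, and 17 of 35 gave as many.

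In 8 of 122 groups of 4 libraries, 1 library lay far from the other 3, where chance gives about 1 in 20. In log2 CPM, Pnpla3 was 6.22 in SSO 1 (others 5.37 to 5.48), Slc25a30 1.96 in SSO 2 (2.86 to 2.97), Col3a1 5.41 in SSO 3 (4.82 to 4.91) and Il6 -2.82 in SSO 4 (-3.24 to -3.22, from 1 or 2 counts each). Creld2 was 5.71 in vehicle 2 (7.26 to 7.48), Elovl6 6.66 in vehicle 2 (5.39 to 5.56), Pltp 3.50 in vehicle 3 (at most 3.92 in the others) and Ifit1 3.18 in vehicle 4 (7.88 to 8.22).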

How the results depend on the processing

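Voom with quality weights and the fit without mitochondrially encoded genes were chosen after seeing the data; all other alternatives were fixed earlier. No gene called in the reported tests changed its sign under any setting. With HFD, edgeR called 361 genes; the number was 926 with DESeq2, 672 without a filter on low counts, 135 when a fold change had to be exceeded (glmTreat) and 86 to 681 with 1 library left out. With SSO, edgeR called 71; the number was 37 with scaling by library size only, 1186 with DESeq2, 205 without a filter, 0 with glmTreat (1184 unadjusted), 2274 with voom quality weights and 0 to 2646 with 1 library left out. The higher and lower calls numbered 249 and 112 with HFD, but 522 and 404 with DESeq2, 399 and 273 without a filter and 336 and 60 with library size only; with SSO 50 and 21, but 450 and 736, 104 and 101, and 33 and 4. Camera with an estimated correlation called 0 lists in either comparison and fry 3 and 2, against 13 and 14; with 1 library left out camera called 11 to 14 and 14 to 17. The overlap of 11 genes became 39 at an adjusted p under 0.1 and 186 with DESeq2. Ern1, not called, had log2 fold changes with HFD of -0.11 to 0.26 with 1 library left out (-0.05 without chow 2, -0.07 without HFD 1, -0.03 without HFD 2), and with SSO of -0.048 with library size only. The acute phase list had camera adjusted p of 5.30e-09 to 0.276, lying the other way without chow 3. Fewer libraries enter each left-out fit; otherwise the cause was not tested. A replicate block gave 206 and 47 genes; same-numbered libraries did not deviate together, with correlations of -0.11 to 0.03, and only vehicle 1 correlated best with its own number. Comparisons of sorted macrophages and their alternatives were not run, and a pseudocount does not apply to counts. Depth limits Il6, with 5 counts over the SSO libraries.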

Other observations

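All genes in this part were chosen after their values were seen, and no test of a theme was made for them.

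In HFD livers Gnmt, which methylates glycine, fell from 1490 to 575 CPM, Bhmt, which remethylates homocysteine, from 4397 to 1550 CPM and Ahcy, which splits adenosylhomocysteine, from 1616 to 740 CPM (edgeR adjusted p = 0.00989, 0.0307 and 0.0215). Cth, cystathionine gamma-lyase, fell from 525 to 165 CPM, the serine dehydratase Sds fell with a log2 fold change of -1.72, and the proline dehydrogenase Prodh fell from 244 to 120 CPM (edgeR adjusted p = 0.0106, 0.00375 and 0.00786). Only Sds was called in all 6 fits with 1 library left out. Without HFD 1 none of the others was called, nor Gnmt and Cth without HFD 3, Bhmt without HFD 2 or 3, and Ahcy without chow 2, HFD 2 or HFD 3 (edgeR adjusted p up to 0.0893 for Gnmt, 0.155 for Bhmt, 0.151 for Ahcy, 0.0877 for Cth and 0.0680 for Prodh).

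The cell cycle inhibitor Cdkn1a rose from 12.3 to 65.5 CPM and Phlda3, which restrains AKT signalling, from 1.65 to 6.70 CPM in HFD livers (edgeR adjusted p = 0.0206 and 0.0440). Cdkn1a was not called without chow 1, chow 3 or HFD 1, nor Phlda3 without chow 2, chow 3 or any 1 HFD library (edgeR adjusted p up to 0.0765 and 0.147). Lipoprotein lipase, Lpl, rose from 34.6 to 66.0 CPM and the chemokine Cxcl10 from 0.668 to 3.45 CPM (edgeR adjusted p = 0.0392 and 0.0246). Lpl was not called without chow 2, chow 3 or any 1 HFD library, nor Cxcl10 without chow 2, HFD 1 or HFD 3 (edgeR adjusted p up to 0.188 and 0.129).

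In SSO livers Pltp, a phospholipid transfer protein, and Mid1ip1, a partner of acetyl-CoA carboxylase, rose with log2 fold changes of 1.18 and 1.31 (edgeR adjusted p = 0.0416 and 0.0369). Both calls were lost without vehicle 1, vehicle 3 or any 1 SSO library (edgeR adjusted p up to 0.161).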
